A study of Mus musculus with 6 samples.

How the data were processed

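RNA-seq libraries from B cells of female B6 mice were grouped by the treatment label into 3 FTY720 and 3 vehicle libraries, and replicate numbers were taken from the mouse label. Per the labels' protocols B cells were isolated with a magnetic B cell isolation kit, RNA was extracted with a column kit, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes the tools were bcl2fastq 2.18.0.12, cutadapt 1.12, STAR 2.5.2b and R 3.3.1. The genome build and annotation are not given in the sources used here, so no coordinates are printed.

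The deposited matrix held whole-number counts for 46983 genes, and the authors' STAR output per library held the same genes with unstranded, sense and reverse-strand counts. The deposited counts equalled the reverse-strand column for each of the 46983 genes in each library, which is the setting that a stranded kit of this type needs, and the sense column held 3.56 to 3.67% as many counts. No per-sample column of the matrix was left unused. Of the reads, 79.0 to 80.7% were counted in genes, and 9.82 to 11.2% overlapped no annotated exon on the counted strand. Another 5.58 to 6.25% mapped to several places, and 1.53 to 1.57% were ambiguous between genes. Unmapped reads made up 2.17% in FTY720 library 1 against 1.61 to 1.79% in the other 5. Rows that name no gene stayed out of library sizes and tests. STAR counts only reads that map to 1 place, so reads of near-identical genes such as antibody segments are lost or split. Ensembl gene identifiers were matched without version to GENCODE M21 names, giving a symbol for 46488 of 46983 (37902 with the same version).

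Total gene counts ranged from 48904572 to 56708879 per library. Intervals at 95% for fold changes come from the spread between libraries, and counts are of reads, which are not independent molecules. No 2 libraries were identical. Over genes with at least 10 summed counts, the chi-square per degree of freedom ranged from 4.65 to 33.1 over the 15 pairs of libraries, above the sampling noise in each, so no pair was treated as repeat deposits of 1 library.

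Counts were tested with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood test, TMM normalization, default filter by expression, robust option off, two-sided), which kept 14369 genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are FTY720 minus vehicle on the log2 scale, and CPM values use TMM-scaled library sizes. The main model had treatment only, and the alternative added the mouse number as a block. The labels give the same mouse to the same-numbered FTY720 and vehicle libraries, while the treatment protocol describes dosed mice and separate control mice. How B cells of a single mouse came to carry both treatments is not given in the sources used here, so a number could also stand for a matched set of animals. Going by the mouse label the numbers were read as pairs. The correlations of deviations were 0.24, 0.33 and 0.04 for the same-numbered libraries, and the low value of number 3 is a limit of that reading. If each library is not a separate animal, p-values measure the spread between these libraries, which may be technical.

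Before the data were examined, 40 gene lists were fixed for B cell biology, sample quality and other cell types, of which 38 had at least 5 tested genes. The mast cell list (1 of 9 genes tested) and the stromal list (4 of 15) were not tested in the main model, but had at least 5 tested genes in 1 and 5 of the alternatives. Cyr61 and Ahsp had no matching symbol. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, beside camera with an estimated correlation and fry. Genes to be named were fixed by rule: a set of S1P, trafficking and B cell genes in any case (2 of them are not reported here), the 3 members with the smallest p from each list that passed, and, since fewer than 10 genes passed, the 10 genes with the smallest p and an average log2 CPM of at least 1. Alternatives were the block, DESeq2 1.42.0 size factors, no filter, a CPM of at least 1 in at least 3 samples, unstranded counts, each library left out, DESeq2 with and without the block, limma-voom, robust dispersion, the block with both libraries of a number left out, and a threshold of 0.1. Figures were drawn with matplotlib 3.10.9.

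The procedure was tested on simulated data. In negative binomial counts made from the real means, dispersions and library sizes for FTY720 against vehicle, over 14185 genes with 50 changed genes per size, 22% of changes of 0.32 on the log2 scale, 88% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes were recovered, with 19 false calls. Changed genes were drawn only from those with an average log2 CPM of at least 1. With no change simulated, 0 of 14191 genes passed and 705 had an unadjusted p under 0.05. In a simulated 1.2-fold shift of a single list, camera called that list and 2 others with the preset correlation, and 0 others with an estimated correlation. Each gene was simulated independently, so recovery of a shift in lists of correlated genes was not measured. In the real data the estimated correlation was 0.82 for the ribosomal and 0.84 for the interferon list. It was 0.52 for the oxidative phosphorylation and 0.22 for the MHC class II list. Gene span, transcript length and GC content were taken from the GENCODE M21 annotation for 99.8% of the genes with an average log2 CPM of at least 1.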

Results

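RNA-seq gene counts were analysed for 6 B cell libraries from B6 mice in an experimental autoimmune encephalomyelitis study of FTY720 (fingolimod), a drug that, once phosphorylated, binds receptors for the lysophospholipid sphingosine-1-phosphate (S1P). There were 3 FTY720 and 3 vehicle libraries, numbered by mouse, so that each of the numbers 1, 2 and 3 had 1 library of each treatment. Per the labels' protocols the drug was given by mouth each day at 1 mg/kg, and vehicle control mice had been immunized with MP4, a fusion of myelin basic protein and proteolipid protein. The organ from which the B cells were isolated is not given in the sources used here. The gene counts summed to 49345618, 56708879 and 48904572 in FTY720 libraries 1, 2 and 3, and to 51598428, 54697636 and 54419248 in vehicle libraries 1, 2 and 3. The summed level of 20 T cell marker genes was 109 ± 12.0 CPM (SD, n = 3) with FTY720 and 109 ± 11.3 CPM (SD, n = 3) with vehicle. FTY720 library 1 stood apart from the other libraries on the leading principal component of log2 CPM, which held 35.9% of the variance, and its 318 genes spanning over 200 kb had a median log2 deviation of -0.51 from their mean over the libraries, against -0.03 to 0.20 in the other 5.

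The question of which B cell transcripts respond to FTY720 was addressed by comparing the 3 FTY720 with the 3 vehicle libraries over 14369 genes. No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test (0 higher, 0 lower, smallest adjusted p = 0.9999). At an unadjusted p under 0.05 there were 140 genes, 74 higher and 66 lower with FTY720, where uniformly distributed p-values would give 718. DESeq2 called 0 genes and had 99 at an unadjusted p under 0.05, and limma-voom called 0 and had 145. The median absolute log2 fold change was 0.05. Among the 10726 genes with an average log2 CPM of at least 1, the 95% interval of the fold change lay within 1.5-fold in either direction for 10209 (95.2%), within 0.32 on the log2 scale for 8087 (75.4%) and within 2-fold for 10697 (99.7%). In real counts thinned to known fold changes in 50 genes per size among 14369 genes, the same test of FTY720 against vehicle recovered 24% of changes of 0.32 on the log2 scale, 72% of 1.5-fold, 92% of 2-fold and 100% of 4-fold. With the mouse number as a replicate block the same simulation recovered 42%, 90%, 98% and 100%, with 2 false calls against 0. The changed genes were drawn from those with an average log2 CPM of at least 1, so recovery among less expressed genes was not measured.

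The tested transcripts of S1P receptors and of S1P metabolism did not pass the test. S1pr1 (ENSMUSG00000045092), the receptor that lymphocytes need to leave lymphoid organs, was measured at 785 ± 12.4 CPM (SD, n = 3) with FTY720 and 809 ± 5.16 CPM (SD, n = 3) with vehicle. Its log2 fold change was -0.04 with a 95% interval from -0.14 to 0.05, and it was lower with FTY720 in 3 of 3 same-numbered pairs. S1pr4 (ENSMUSG00000044199) stood at 262 ± 2.95 CPM (SD, n = 3) and 262 ± 8.89 CPM (SD, n = 3), with an interval from -0.11 to 0.10. The less expressed receptors S1pr2 and S1pr3 had log2 fold changes of 0.09 and 0.12, with wider intervals of -0.28 to 0.47 and -0.23 to 0.47. Sphk2 (ENSMUSG00000057342), a sphingosine kinase that phosphorylates FTY720, had a log2 fold change of -0.02 with an interval from -0.14 to 0.09. Sgpl1, the lyase that degrades S1P, had a log2 fold change of -0.03 with an interval from -0.15 to 0.09. Sphk1 had counts of 0, 0 and 3 in the FTY720 libraries and 1, 0 and 1 in the vehicle libraries and was below the limit for testing. Of 25 tested genes of the S1P receptor and metabolism list, 14 had a fold change above 0 and 11 below, and 0 passed with adjustment over all genes or adjusted over the list alone. The receptor gene S1pr5 was not among these 25.

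**Figure D1:**
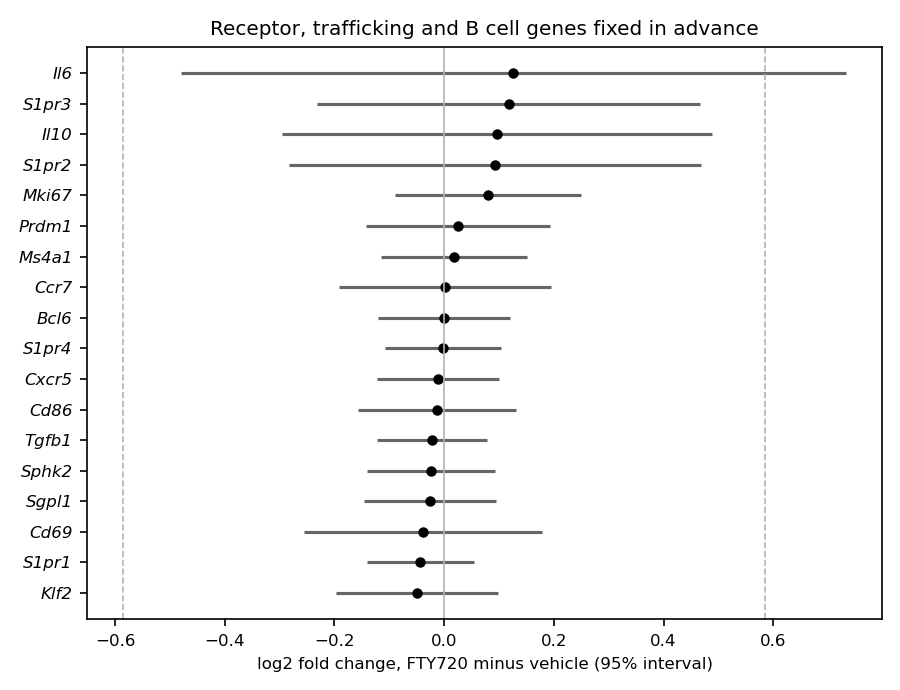
Log2 fold change (FTY720 minus vehicle, x axis) of 18 tested genes among those fixed in advance, with the edgeR estimate as a point and the 95% interval as a line, and dashed lines at 1.5-fold in either direction. The intervals are from the fit without a block. Each interval covers 0, and the interval of Il6, from -0.48 to 0.73, is the widest.

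Genes that position B cells did not pass the test either. Klf2 (ENSMUSG00000055148), a transcription factor that maintains S1pr1 expression, had a log2 fold change of -0.05 (95% interval -0.20 to 0.10). The follicle homing receptor Cxcr5 was at -0.01 (-0.12 to 0.10) and the lymph node homing receptor Ccr7 at 0.00 (-0.19 to 0.20). Cd69, an activation marker whose protein removes S1PR1 from the cell surface, was at -0.04 (-0.26 to 0.18). In the trafficking list 19 of 27 tested genes had a fold change below 0, with 0 genes past the test with either adjustment (camera adjusted p = 0.442 for the list). The 95% interval lay within 1.5-fold in either direction for 24 of the 27. The chemokine receptor genes Ccr10 and Ccr9, chosen after their values were seen, had log2 fold changes of -0.74 ± 0.41 and 0.37 ± 0.22 (SE). Leaving out single libraries turned the sign of the Klf2, Cxcr5, Ccr7 and Cd69 estimates, and of S1pr3, S1pr4 and Sphk2 among the S1P genes.

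B cell identity, activation and differentiation genes showed no change past the test. Ms4a1, which encodes the B cell surface protein CD20, was at 1322 ± 1.68 CPM (SD, n = 3) with FTY720 and 1306 ± 99.3 CPM (SD, n = 3) with vehicle. The costimulatory gene Cd86 had a log2 fold change of -0.01 (95% interval -0.16 to 0.13), the germinal centre regulator Bcl6 of 0.00 (-0.12 to 0.12), the plasma cell regulator Prdm1 of 0.02 (-0.14 to 0.19) and the proliferation marker Mki67 of 0.08 (-0.09 to 0.25). Among cytokine genes, Tgfb1 was at 279 ± 5.91 CPM (SD, n = 3) and 283 ± 4.88 CPM (SD, n = 3). Il10 was at 6.03 ± 1.62 CPM (SD, n = 3) with FTY720 and 5.64 ± 0.129 CPM (SD, n = 3) with vehicle, and Il6 at 5.32 ± 1.54 CPM (SD, n = 3) and 4.88 ± 1.5 CPM (SD, n = 3). In the fit without a block the 95% interval of Il10 (-0.29 to 0.49) lay within 1.5-fold in either direction. That of Il6 (-0.48 to 0.73) reached beyond it. Il6 also differed between the mouse numbers, which widens its interval in that fit. With the mouse number as a replicate block its log2 fold change was 0.13 ± 0.12 (SE). Leaving out single libraries turned the sign of the Ms4a1, Cd86, Bcl6, Prdm1, Il10 and Il6 estimates.

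The 10 genes with the smallest p among those with an average log2 CPM of at least 1 are given as values, since none passed (adjusted p = 0.9999 in edgeR's quasi-likelihood test). Ighg2c (ENSMUSG00000076612), the constant region of the B6 form of IgG2a, had a log2 fold change of -2.59 ± 0.78 (SE), at 0.916 ± 0.187 CPM (SD, n = 3) with FTY720 and 5.50 ± 6.40 CPM (SD, n = 3) with vehicle. Its log2 fold change ranged from -3.07 to -1.0 over 15 alternatives, and was -1.0 without vehicle library 1, which held 665 of its counts. The antibody variable segments Ighv8-5 and Igkv6-23 had log2 fold changes of -0.41 ± 0.13 (SE) and -0.15 ± 0.05 (SE), and near-identical segments can share reads with them. Xist (ENSMUSG00000086503), the noncoding RNA of X inactivation, was at 729 ± 32.7 CPM (SD, n = 3) with FTY720 and 656 ± 18.3 CPM (SD, n = 3) with vehicle, a log2 fold change of 0.15 ± 0.05 (SE). Tmc4 was at 0.28 ± 0.09 (SE) and Hs1bp3 at -0.27 ± 0.09 (SE). The noncoding or uncharacterised genes BE692007, F730311O21Rik, 4930581F22Rik and ENSMUSG00000102171 had log2 fold changes of 0.18, 0.21, 0.48 and 0.40. Each of these 10 had the same sign in 3 of 3 pairs, which choosing them by small p in the same libraries favours, so it adds no support.

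Of 38 gene lists tested, 4 passed an adjusted p of 0.05 in camera with a preset correlation between genes of 0.01. The type I interferon response list was higher with FTY720, with 23 of 24 genes above 0 and a median log2 fold change of 0.12 (adjusted p = 0.0342). The cytosolic ribosomal protein list was lower, with 29 of 29 genes below 0 and a median of -0.05 (adjusted p = 2.59e-05). The MHC class II presentation list was lower, with 15 of 16 genes below 0 and a median of -0.04 (adjusted p = 0.0114). The list of nuclear-encoded oxidative phosphorylation genes was lower, with 21 of 24 genes below 0 and a median of -0.04 (adjusted p = 0.0150). None of the 4 calls held with an estimated correlation (adjusted p = 0.979 in each), and on all 6 libraries none of their genes passed with adjustment over all genes or adjusted over the list alone. In the interferon list, Stat2, Ifih1 and Ddx58, which encode a signal transducer and sensors of viral RNA, had log2 fold changes of 0.10 ± 0.06, 0.24 ± 0.22 and 0.09 ± 0.09 (SE). The antigen-presenting genes H2-Aa and H2-Eb1 and the endosomal protease gene Lgmn were at -0.07 ± 0.06, -0.06 ± 0.05 and -0.09 ± 0.05 (SE). Rpl3, Rpl6 and Rps9 were at -0.07, -0.06 and -0.07, and the respiratory chain genes Ndufb3, Ndufa1 and Sdhb at -0.17, -0.11 and -0.06.

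The interferon median was above 0 in each of the 3 pairs (0.02, 0.06 and 0.26). In the same pairs the medians of neutrophil markers were -0.20, -0.27 and 0.39, those of monocyte and macrophage markers -0.24, -0.20 and 0.22, and those of dendritic cell markers -0.47, 0.03 and 0.19, so that each of these lists was also highest in pair 3. That was not particular to them, as platelet markers (0.47), cell cycle genes (0.13) and T cell markers (0.12) were also highest in pair 3. Other lists, such as mitochondrially encoded genes (-0.33), were lowest there. With the mouse number as a replicate block the interferon list's adjusted p was 1.77e-10 in camera with the preset correlation, and that call too was lost (adjusted p = 0.987 with an estimated correlation). In the fit without a block, leaving out a single library unbalanced the mouse numbers, between which 14 of the list's 24 genes differed in edgeR. Over 14 alternatives the adjusted p ranged from 3.08e-15 to 0.987 for the interferon, 1.99e-12 to 0.987 for the ribosomal, 0.00191 to 0.987 for the MHC class II and 0.0001 to 0.987 for the oxidative phosphorylation list. Without vehicle library 2 the median log2 fold change of the list was -0.04 with an adjusted p of 0.121, without FTY720 library 3 it was 0.01 with 0.908, and without FTY720 library 1 it was 0.05 with 0.768. The ribosomal median was above 0 in pair 1 (0.07) and below 0 in pairs 2 and 3 (-0.07 and -0.13), and the oxidative phosphorylation median was 0.05, -0.06 and -0.09. The MHC class II median was below 0 in each of the 3 pairs (-0.07, -0.06 and -0.05). That call ended without FTY720 library 1, vehicle library 2 or FTY720 library 3, with adjusted p of 0.136, 0.451 and 0.140. The ribosomal call ended without FTY720 library 2 (0.226) or vehicle library 3 (0.563), and the oxidative phosphorylation call ended without FTY720 library 2 (0.579), FTY720 library 3 (0.0931) or vehicle library 3 (0.783). With no filter on low counts the interferon (0.0861) and oxidative phosphorylation (0.0790) calls also ended on all 6 libraries.

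**Figure D2:**
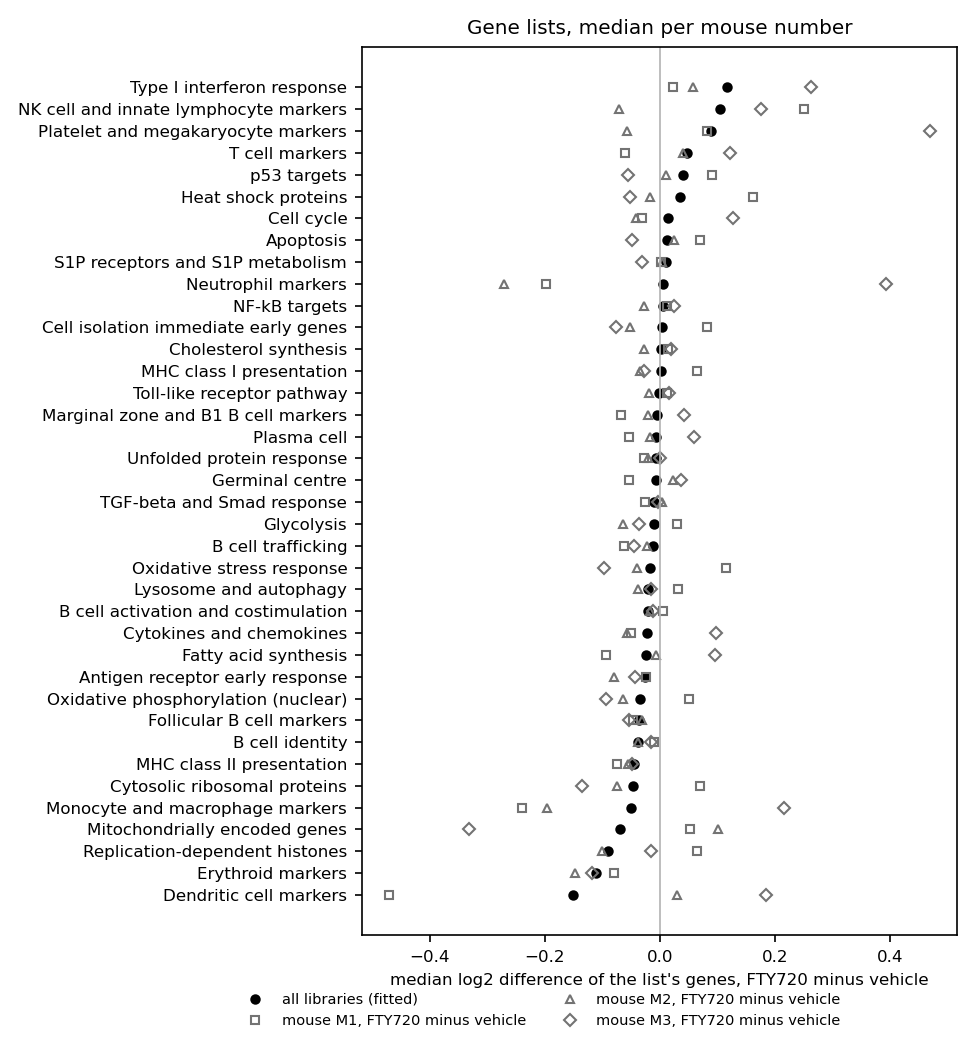
Median log2 difference of each tested list's genes (FTY720 minus vehicle, x axis), with the fitted value over all libraries as a filled point and the difference within each mouse number as open symbols. The fitted medians lie between -0.15 and 0.12, and those of neutrophil markers by number lie at -0.20, -0.27 and 0.39.

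**Figure D3:**
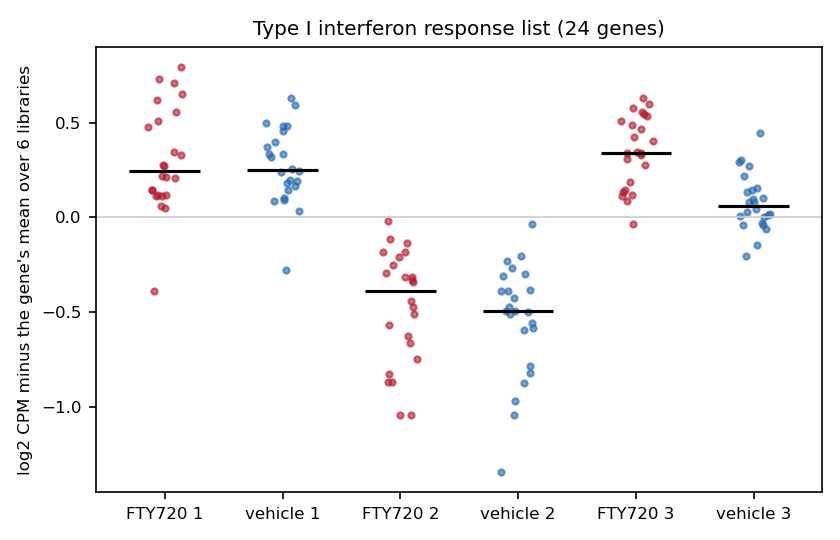
Log2 CPM of the 24 type I interferon response genes in each library, centred on each gene's mean over the 6 libraries (y axis), with 1 point per gene and the median as a bar. The medians were 0.24 and 0.25 in number 1, -0.39 and -0.49 in number 2, and 0.34 and 0.06 in number 3, for FTY720 and vehicle.

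The other 34 lists did not pass, with camera adjusted p from 0.296 to 0.979, and none of them passed with an estimated correlation (adjusted p = 0.979). Among B cell lists, identity genes had a median log2 fold change of -0.04 (7 of 20 above 0), follicular markers -0.04 (1 of 10), marginal zone and B1 markers -0.01 (6 of 18), activation and costimulation genes -0.02 (7 of 25), early antigen receptor response genes -0.03 (6 of 19), NF-kB targets 0.01 (11 of 20) and germinal centre genes -0.01 (6 of 15). The Toll-like receptor pathway was at 0.00 (9 of 19), cytokines and chemokines at -0.02 (9 of 19), TGF-beta response genes at -0.01 (7 of 16) and MHC class I presentation at 0.00 (9 of 16). Metabolic lists lay close to 0, with cholesterol synthesis at 0.00 (12 of 23), fatty acid synthesis at -0.02 (6 of 13), glycolysis at -0.01 (6 of 17) and lysosome and autophagy at -0.02 (8 of 25). Cell cycle genes were at 0.02 (15 of 25), apoptosis genes at 0.01 (15 of 22), p53 targets at 0.04 (14 of 15), unfolded protein response genes at -0.01 (10 of 22) and oxidative stress genes at -0.02 (7 of 19). Of the lists on RNA and sample quality, that of cytosolic ribosomal proteins passed as given above, and the others did not pass on all 6 libraries, with heat shock proteins at 0.03 (9 of 14), isolation-induced immediate early genes at 0.00 (9 of 17), mitochondrially encoded genes at -0.07 (4 of 12) and replication-dependent histones at -0.09 (7 of 17). Without FTY720 library 1, camera with the preset correlation called the immediate early (adjusted p = 1.75e-05), heat shock (0.0160) and mitochondrially encoded (0.0276) lists lower with FTY720, and without vehicle library 2 the mitochondrially encoded list (0.000553). Over 14 alternatives their adjusted p ranged from 1.75e-05 to 0.989, 0.0160 to 0.987 and 0.000553 to 0.987. The fits without a single library had no block and so unbalanced the mouse numbers. The camera direction differed in sign from the median for histones (up), neutrophil markers, immediate early genes, cholesterol synthesis and S1P genes (each down), germinal centre genes and the Toll-like receptor pathway (each up). It differed from the mean for histones (-0.01), immediate early genes (0.01), fatty acid synthesis (0.03), TGF-beta response (0.01), marginal zone and B1 markers (0.00), cholesterol synthesis (0.00) and S1P genes (0.00). In these and in the marker lists, 0 genes passed with adjustment over all genes or adjusted over the list alone.

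Markers of other cell types did not pass a test between the treatments on all 6 libraries. Neutrophil markers summed to 31.2 ± 17.0 CPM (SD, n = 3) with FTY720 and 31.9 ± 20.1 CPM (SD, n = 3) with vehicle. Monocyte and macrophage markers summed to 413 ± 71.1 CPM (SD, n = 3) and 414 ± 53.8 CPM (SD, n = 3), and dendritic cell markers to 124 ± 15.4 CPM (SD, n = 3) and 129 ± 26.6 CPM (SD, n = 3). Erythroid markers summed to 149.9 ± 14.6 CPM (SD, n = 3) and 149 ± 8.83 CPM (SD, n = 3), and platelet markers to 21.3 ± 1.90 CPM (SD, n = 3) and 19.9 ± 1.15 CPM (SD, n = 3). NK and innate lymphocyte markers summed to 7.01 ± 0.263 CPM (SD, n = 3) and 6.60 ± 0.743 CPM (SD, n = 3). Median log2 fold changes were 0.05 for T cell, 0.01 for neutrophil, -0.05 for monocyte and macrophage, -0.15 for dendritic cell, -0.11 for erythroid, 0.09 for platelet and 0.10 for NK cell markers. In camera with the preset correlation, monocyte and macrophage markers were called lower without FTY720 library 1, vehicle library 2 or FTY720 library 3 (adjusted p from 0.00124 to 0.991 over 14 alternatives). Erythroid markers were called lower without FTY720 library 1 or vehicle library 3 (0.00419 to 0.9998), and T cell markers higher without FTY720 library 1 or vehicle library 2 (0.000581 to 0.987). Neutrophil markers were called higher without vehicle library 1 or FTY720 library 2 and lower without vehicle library 2 (6.56e-05 to 0.9998). Dendritic cell markers were called higher without vehicle library 1 and lower without vehicle library 2 (0.0237 to 0.987). With an estimated correlation lists were tested on all 6 libraries, not without single libraries.

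Among plasma cell genes the 3 IgG subclass genes with the smallest p differed in direction. Per library the counts of Ighg2c were 55, 43 and 43 with FTY720 and 665, 137 and 62 with vehicle for numbers 1, 2 and 3. Ighg2b (ENSMUSG00000076613) had 329, 813 and 803 counts with FTY720 and 322, 431 and 450 with vehicle, and Ighg1 (ENSMUSG00000076614) had 142, 135 and 44 against 51, 56 and 47. Ighm, the IgM heavy chain gene of resting B cells, had a log2 fold change of -0.05 ± 0.05 (SE), and Jchain, which encodes the joining chain of secreted antibodies, of -0.21 ± 0.14 (SE). In the fit without a block 0 of 23 plasma cell list genes passed adjusted over the list alone (smallest adjusted p = 0.181), and the list's median was -0.01 with 11 of 23 above 0. With the mouse number as a replicate block, 3 of 23 passed adjusted over the list alone in edgeR's quasi-likelihood test: Ighg2c (log2 fold change -2.13 ± 0.40 SE, adjusted p = 0.00345), Ighg2b (0.67 ± 0.14 SE, adjusted p = 0.00454) and Ighg1 (1.00 ± 0.26 SE, adjusted p = 0.0168). Over all genes 0 passed with the block (adjusted p = 0.9999). Leaving out both libraries of number 1 moved the blocked Ighg2c value to -1.12. Ighg3 (ENSMUSG00000076615), which was not in the list, had 730, 703 and 458 counts with FTY720 and 645, 740 and 522 with vehicle, and a blocked log2 fold change of 0.02 ± 0.10 (SE) with pair differences of 0.25, -0.14 and -0.06. Ighg2b, Ighg1 and Ighg3 were chosen after their values were seen, and reads from the closely related IgG constant regions can be assigned to the wrong subclass.

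**Figure D4:**
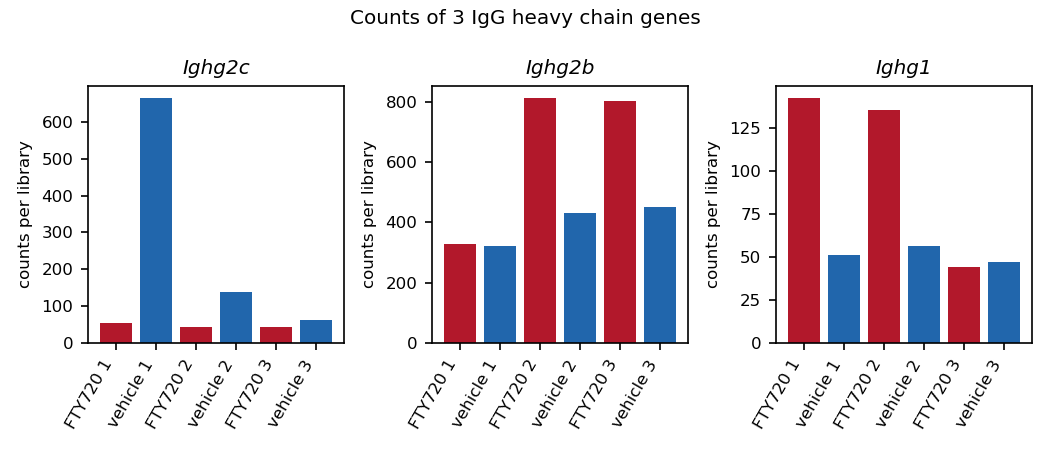
Counts per library (y axis, from 0) of the IgG constant region genes Ighg2c, Ighg2b and Ighg1 in the 3 FTY720 libraries (red) and 3 vehicle libraries (blue), by mouse number. Ighg2c is highest in vehicle library 1 with 665 counts, and Ighg2b in FTY720 libraries 2 and 3 with 813 and 803.

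Libraries with the same mouse number deviated together in 2 of the 3 pairs. Across genes, which are not independent replicates, the deviations of log2 CPM from the group mean had a Pearson correlation of 0.24 between the libraries of number 1, 0.33 for number 2 and 0.04 for number 3, against -0.27 to 0.05 between libraries of different numbers.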

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

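None of the alternatives was chosen after the results were seen. The count of 0 genes past the threshold held under each alternative run on all 6 libraries and without each single library (smallest adjusted p from 0.0713 to 1, where 0.0713 was reached without FTY720 replicate 1). With the mouse number as a replicate block 0 genes passed and 236 had an unadjusted p under 0.05, against 140 without it, and among the gene lists the block kept the number of calls at 4. The block changed no other call over all genes, and adjusted over the list alone it added the 3 IgG genes. Other settings called 0 genes with 143 (DESeq2 size factors), 337 (no filter), 65 (stricter filter), 158 (unstranded), 99 (DESeq2), 49 (DESeq2 with block), 145 (limma-voom) and 141 (robust) at an unadjusted p under 0.05. In edgeR the block with both libraries of a number left out called 15 genes without number 1, 1 without number 2 and 1 without number 3. Ighg2c was called in each of these 3 fits of 2 pairs, with log2 fold changes of -1.12, -2.25 and -2.79 against -2.13 on all 3 pairs (adjusted p = 0.0446, 0.000873 and 4.09e-06). These fits share libraries and measure little of each gene's own spread, so their p-values rest largely on the spread of other genes. That is a limit for Ighg2c, whose dispersion was at percentile 99.8 among genes of like expression. The 15 genes without number 1, named after their values were seen, were 6 higher, Ighg2b (0.91 on the log2 scale, adjusted p = 1.95e-14), the interferon list gene Mx1 (0.52, 0.00112), Thbs1, Igkv8-18, Rnf213 and Malat1, and 9 lower, Ighg2c, the mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 (-0.27 each), Lars2, Mir6236, Gm23935 (adjusted p = 7.74e-22), Gm24270, Gm24187 and Gm15564. The cause was not tested.

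The number of lists called was 2 with no filter, MHC class II and ribosomal proteins, 0 in camera with an estimated correlation, 0 in fry and 0 with an estimated correlation and the replicate block, where correlation within the lists is counted against them. Leaving out single replicates, in fits without a block that unbalanced the mouse numbers, gave 2 to 11 lists. There were 2 without FTY720 replicate 3, 9 without vehicle replicate 2 and 11 without FTY720 replicate 1. Besides quality and cell type lists, these fits called antigen receptor early response lower in 2, lysosome and autophagy lower in 1, stromal markers, tested in 5 of the alternatives, lower without vehicle replicate 2 (adjusted p = 0.00374, range to 0.830), and oxidative stress response lower in 2 and higher in 1. The median log2 fold change ranged from -0.044 to 0.37 for the interferon list and from -0.063 to 0.0028 for oxidative phosphorylation. Over 14 alternatives the ribosomal call was kept in 9, MHC class II in 8, oxidative phosphorylation in 7 and interferon in 7. The cause was not tested.

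Of 40 named genes 13 changed sign in at least 1 of 15 alternatives, and 0 values passed the threshold in those 15, which leave out the 3 blocked fits without a number. With all 6 libraries this concerned Ccr7 (-0.00085 with the block, -0.00034 unstranded, -0.0017 in DESeq2 with the block, -0.0013 in limma-voom), S1pr4 (0.00076 with no filter) and Bcl6 (0.0020 with no filter, 0.00026 with the stricter filter, 0.0011 unstranded). Without single replicates the log2 fold changes ranged from -0.090 to 0.068 for Ccr7, -0.021 to 0.029 for S1pr4, -0.038 to 0.028 for Bcl6, -0.047 to 0.23 for S1pr3, -0.11 to 0.35 for Il6, -0.16 to 0.042 for Cd69, -0.051 to 0.0097 for Sphk2, -0.057 to 0.034 for Cd86, -0.10 to 0.0089 for Klf2, -0.025 to 0.079 for Ms4a1, -0.041 to 0.023 for Cxcr5, -0.14 to 0.22 for Il10 and -0.021 to 0.074 for Prdm1. The cause was not tested. Depth limits genes with few counts, such as Sphk1.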

Other observations

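The tests of mouse number, pairings, gene span, IgG genes and splits were chosen after the values they measure had been seen. Results of the test of treatment, with and without the block, are repeated here from the planned fits. In edgeR's quasi-likelihood test of the mouse number, with treatment in the model, 109 of 14369 genes passed an adjusted p of 0.05, and 79 of them were lowest in number 2. Type I interferon response genes made up 14 of them, out of 24 tested (Fisher's exact test over genes, which are not independent, one-sided, adjusted p = 6.16e-23 over 38 lists). Ifit3, an interferon-induced antiviral gene, averaged 16.8, 5.19 and 14.1 CPM in numbers 1, 2 and 3, Irf7, a transcription factor that amplifies the interferon response, 52.4, 19.3 and 39.9 CPM, and Oas2 25.1, 9.89 and 22.1 CPM. Between the treatments Irf7 was at 56.6 and 48.3 CPM in the FTY720 and vehicle libraries of number 1, 18.7 and 19.8 in number 2, and 45.2 and 34.6 in number 3, with 0 of the genes in the interferon list past the test of treatment on all 6 libraries.

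Neutrophil markers made up 7 of the 109, out of 11 tested (adjusted p = 7.27e-12), and erythroid markers 4 out of 11 (adjusted p = 1.26e-05). The monocyte and macrophage list had 2 of 18 and did not pass (adjusted p = 0.0568). Its summed levels in the FTY720 and vehicle libraries were 468 and 466 CPM in number 1, 333 and 359 in number 2, and 439 and 416 in number 3. Dendritic cell markers had 1 of 10 (adjusted p = 0.348), with sums of 131 and 158, 107 and 107, and 136 and 121 CPM. The granule gene Ngp averaged 7.48, 0.943 and 4.37 CPM in numbers 1, 2 and 3, and S100a9 14.5, 3.22 and 10.4 CPM. Of macrophage genes outside the fixed lists, chosen after their values were seen, Cd5l averaged 12.7, 2.58 and 7.83 CPM and Marco 10.9, 5.03 and 7.60 CPM. Hbb-bs was lowest in number 3 (28.4, 30.1 and 19.3 CPM). Il6 was lowest in number 1 (3.35, 5.97 and 5.98 CPM), as was Sdc1, a plasma cell surface marker (47.3, 72.2 and 64.9 CPM).

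The other 5 pairings of FTY720 and vehicle libraries gave 0 genes in edgeR, with 91 to 1376 at an unadjusted p under 0.05 against 1669 for the numbers as labelled. Only 1 of the 6 pairings gave as many as 109, and 6 pairings are too few for a share under 0.05. Carried-over neutrophils, monocytes, macrophages or dendritic cells, whose summed markers were also lowest in number 2, stay open as a source of the interferon genes, since no table here holds the level of these genes in such cells. Summed T cell markers were instead highest in number 2, and erythroid markers lowest in number 3. Vehicle library 1 exceeded FTY720 library 1 in neutrophil (52.8 against 44.0 CPM) and dendritic (158 against 131 CPM) sums, but not in the interferon sum (919 against 949 CPM). In number 3 these 3 sums were all higher in the FTY720 library. The B cell isolation kit is meant to remove cells other than B cells, and the summed neutrophil markers, of which 11 of 14 genes passed the expression filter, were at 12.0 to 52.8 CPM. A difference between animals in interferon exposure was not tested and stays open, and a day or batch shared by the libraries of a number cannot be told apart from it.

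In FTY720 library 1 expression was lower in genes of longer genomic span (Spearman's rho = -0.48 across 10705 genes, which are not independent), with median log2 deviations of 0.06 for genes up to 10 kb, -0.21 for 100 to 200 kb and -0.51 for 318 genes over 200 kb. In the other libraries rho ranged from -0.10 in vehicle library 3 to 0.45 in FTY720 library 2. Deviations were taken from the mean over all 6 libraries, so 1 low library raises the others. GC content is argued against, as the median of the genes over 200 kb was -0.45 or lower in each of 5 classes of GC content. Transcript length, or RNA degradation that follows it, is argued against in the same way, with -0.49 or lower in each of 5 classes of transcript length. RNA degradation that does not follow transcript length was not tested and stays open. A response to FTY720 in each mouse is argued against by the medians of the difference from vehicle over these genes, which were -0.52 in number 1, 0.01 in number 2 and 0.17 in number 3. The handling of that library and a response in that mouse alone also stay open, and any of these may account for the pattern.

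Ighg2c and Ighg2b had log2 fold changes of opposite sign, -2.13 ± 0.40 and 0.67 ± 0.14 (SE) under the replicate block. A change in the share of antibody-secreting cells of all subclasses together would move both genes the same way. The opposite signs argue against it as the only account of these 2 genes. Whether that share changed stays open, since the plasma cell list's median of -0.01 over genes that go both ways decides nothing. The summed counts of Ighg2c and Ighg2b were 384 with FTY720 against 987 with vehicle in number 1. They were 856 against 568 in number 2 and 846 against 512 in number 3. The sum was thus lower with FTY720 in 1 pair and higher in 2. The log2 fold change of the sum, 0.056 with a 95% interval from -0.55 to 0.66, averages pairs that go both ways and decides nothing. An exchange of reads between the 2 genes alone would leave each pair's sum unchanged, which was not seen in any of the 3 pairs. Totals may also differ between animals, with 1 library per number and treatment, so reads shared between these genes stay open. Sampling of few antibody-secreting cells also stays open. In the fit without a block the dispersion of the other 20 plasma cell list genes had a median percentile of 51.5 among genes of like expression. That median mixes high and low values and decides nothing. Percentiles were high for Ighg2c (99.8), Ighg2b (98.35), Ighg1 (96.93), Ighg3 (93.56), Jchain (94.24), Igha (88.68), Sdc1 (98.75) and Iglv1 (91.58). They were low for Fkbp11 (15.59), Irf4 (23.49), Txndc5 (24.46), Edem1 (26.86) and Creld2 (27.44). A shift between IgG subclasses with FTY720 is a hypothesis that rests on 3 pairs and on low counts, with Ighg3 at 0.02 ± 0.10 (SE) under the block. It may not survive more animals, as no IgG gene passed over all genes in the fits on all 6 libraries. Under the block Ighg2c did pass without number 1 (where it was at -1.12), 2 or 3, and Ighg2b without number 1. Those fits of 2 pairs share libraries and measure little of each gene's own spread, so they add little.

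For the comparison of FTY720 with vehicle, the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes past the threshold, so each of the 10 had to give as many or more, and this comparison decides nothing. The highest other gave 1. For gene lists in camera with the preset correlation, 8 of the 10 splits gave at least the 4 lists of the real split, and the highest other gave 17. Of the 4 splits that part all 3 same-numbered pairs, the real split included, the other 3 gave 4, 2 and 3 lists. The other 6 splits, which keep 2 pairs together, gave 5 to 17 lists. At an unadjusted p under 0.05 the real split had 140 genes and the others 151 to 2231, which points to a structure of the samples other than treatment.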
